A study of Mus musculus with 12 samples.

How the data were processed

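The deposited values are probe set signals of an Affymetrix mouse array of the 430A 2.0 type, on a linear scale, with intensity as their unit, as the authors gave them. Per the labels, labelled cells were dispersed and sorted by flow cytometry, their total RNA was extracted with QIAzol and amplified with a MessageAmp kit, and biotinylated cRNA was hybridised. Per the submitters' processing notes the signals come from MAS5 and Affymetrix Expression Console, with no version given. The 10th to 99th percentiles of the signal differed between arrays by at most 0.067 (log2), and whether a normalization followed MAS5 is not given in the sources used here. The arrays being this alike, the values were used without another normalization, and log2 was taken. Detection calls were not used here.

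Of 22690 probe sets, 64 controls were left out. By the probe annotation, 20393 probe sets stood for 1 gene, 691 for several and 1542 for none, and only the first kind was used, covering 12394 genes. Symbols were updated through Entrez identifiers for 20364 of them and 29 had no match; no symbol changed, and the gene table belongs to the GRCm38.p6 assembly. A probe set was tested if at least 2 of the 12 arrays lay above that array's median, which 12735 probe sets did, and each gene was represented by its probe set of highest mean (2683 genes had several), which left 7721 genes. Of the genes called between head and trunk over the mean of the 3 stages, 275 had several probe sets that passed the filter, of which 28 had one of opposite sign and 0 were called both ways. At single stages a probe set of opposite sign was found for 11 of 152 such genes at E9.5, 36 of 125 at E10.5 and 0 of 41 at E11.5.

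Differences were tested with limma on log2 signal, with 1 mean per group for the 6 groups, an empirical Bayes fit with an intensity trend, 6 residual and 5.87 prior degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. Called genes are those past that threshold. There were 11 comparisons: head against trunk over the mean of the 3 stages and at each stage, each pair of stages within head and within trunk, and the difference between the tissues in the change from E9.5 to E11.5. The p-values measure only the spread between these samples, since the labels do not say whether the 2 arrays of a group come from separate animals, litters or pools, and the number of arrays limits the precision. A fold is given as a bound ("at least") where any array of the dimmer side lay below the median probe set: such arrays were raised to that median, a conservative floor, and no fold is given where both sides lay there. Log2 values are fitted to the signals without this floor. Where signals lay below the median, an order by log2 value is therefore not an order of measured folds.

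Gene lists were written from textbook knowledge. There were 29 lists with 541 entries, of which 357 were tested: pharyngeal mesoderm regulators, dermomyotome and limb myoblast regulators, sclerotome and tendon, the Hox genes of paralog groups 1 to 4 and of groups 5 to 13, myogenic regulatory factors and cofactors, skeletal muscle differentiation, cardiac progenitor regulators, cardiac contractile genes, neural crest and ectomesenchyme, neurons, neural progenitors, forebrain with midbrain and eye, endothelium, erythroid cells, macrophages and leukocytes, epithelium, cartilage, connective tissue and extracellular matrix, cell cycle, the Notch, Wnt, BMP and TGF-beta, FGF, Hedgehog and retinoic acid pathways, immediate early and heat shock genes, hypoxia and glycolysis, and X inactivation with Y-linked genes. Lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists within a comparison, with the estimated correlation run beside it. Genes are named by a rule: for the mean of the 3 stages, the change from E9.5 to E11.5 in each tissue and the difference between those changes, the 10 genes with the largest and the 10 with the most negative log2 value among the called genes whose arrays go the same way; for each other comparison 5 each way; up to 4 members of smallest p of each list described; and Myf5, Tbx1, Tcf21, Msc, Lhx2, Isl1 and Pax3 in any comparison. For the difference between the changes no condition on single arrays applied. Other genes are marked as named after their values were seen. The groups, the tests, the lists, the rule and the alternatives, except those said to be added later, were fixed before the data were examined. The median log2 value of all genes lay between −0.01 and 0.02 in every comparison. After quantile normalization or median centring it lay between −0.02 and 0.02.

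The test was tried on simulated arrays drawn from the means and the fitted spread of the 7721 genes, with 200 changed genes in each of 5 runs. For head against trunk over the mean of the 3 stages it recovered 90.4% of 2-fold and 98.4% of 4-fold changes, with 4.4% of its calls false. For the change from E9.5 to E11.5 it recovered 53.8% and 96.0% in head (6.4% false) and 52.4% and 93.6% in trunk (5.8% false). For the difference between those changes it recovered 20.8% and 75.8% (4.4% false). No call had the wrong sign, camera found the shifted list in 5 of 5 runs of each comparison, and it called 2, 0, 0 and 1 of 100 unshifted lists. The simulated genes varied independently of each other. These runs therefore do not show how often camera calls unshifted lists whose members vary together. Among the lists examined for this, the mean correlation between members ran from −0.04 for the myogenic factors to 0.57 for erythroid cells. The versions were R 4.3.3, limma 3.58.1, data.table version 1.17.8, Python 3.11.15 and matplotlib 3.10.9.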

Results

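The data describe muscle progenitors of the mouse embryo, taken from the head and from the trunk while both populations form muscle. In ICR embryos carrying Myf5Cre and RosaYFP, cells that have expressed the muscle determination gene Myf5, and their descendants, carry the yellow fluorescent protein, so that a sort on fluorescence collects the labelled cells of each region. Head and trunk cells were collected at embryonic days 9.5, 10.5 and 11.5 (E9.5, E10.5 and E11.5), which gives 6 groups with 2 arrays each, 12 arrays in all. The median signal per array lay between 108.6 and 110.4 intensity units. The 2 arrays of a group correlated across probe sets with Pearson r of 0.957 (head at E10.5) to 0.981 (trunk at E10.5), a description across genes, which are not independent replicates. In a principal component analysis the first component held 31.5% of the variance and placed trunk at E9.5 at −50.1 and −43.9, apart from the other arrays. The second held 26.3% and was highest in head at E9.5. RNA quality did not separate the tissues: the log2 difference between 3′ and 5′ probe sets of Actb averaged 5.49 in head and 5.48 in trunk (exact two-sided permutation test, p = 0.976, adjusted over 3 measures 0.976), and for Gapdh it averaged 5.75 and 5.54 (exact permutation p = 0.147, adjusted 0.221). The third measure, the bacterial spike-in signal, averaged log2 10.21 and 10.03 (exact permutation p = 0.0909, adjusted 0.221). The transcript Xist, which marks cells with an inactive X chromosome, had a log2 signal of 7.35 and 6.37 on replicate 1 of head and of trunk at E10.5, against 11.89 to 13.10 on the other 10 arrays.

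The first question was which transcripts set head apart from trunk muscle progenitors over the mean of the 3 stages. Of 12 tested regulators of the pharyngeal mesoderm, the unsegmented tissue behind head muscle and part of the heart, 10 were higher in head. All 18 tested Hox genes of axial position and 7 of 14 regulators of the dermomyotome, the somite layer that supplies trunk muscle, were higher in trunk. Tbx1, a T-box factor of pharyngeal development, was higher in head by log2 2.66 ± 0.14 (SE from limma, n = 6 arrays per tissue; adjusted p = 4.84e-07), at least 5.43-fold. Isl1, a LIM-homeodomain factor of the second heart field, was 8.07-fold higher (log2 3.01 ± 0.17, adjusted p = 8.56e-07). The basic helix-loop-helix factors of branchial arch muscle, Msc and Tcf21, were at least 6.61-fold and at least 5.46-fold higher (log2 3.04 ± 0.18 and 3.76 ± 0.39, adjusted p at most 6.67e-05). Myf5 itself did not pass the test (log2 0.24 ± 0.12, adjusted p = 0.239). In all, 808 of the 7721 genes tested differed between the tissues over the mean of the 3 stages by limma with Benjamini-Hochberg adjustment, 529 higher and 279 lower in head. Of the genes called at each single stage, 22 were higher and 25 lower in head at all 3 stages. Without trunk E10.5 replicate 2 the count was 534, and without both E10.5 replicate 1 arrays, an omission chosen after the data were seen, it was 446.

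Of the 12 tested pharyngeal mesoderm regulators 10 were higher and 1 lower in head, also when adjusted over the list alone, and the list's median was log2 2.43 (camera, adjusted p = 6.08e-12; 0.00858 with an estimated correlation). This list was not blind to the study, whose title names a pharyngeal mesoderm network. Lhx2 (log2 4.81 ± 0.39, at least 2.22-fold), Tlx1 (3.22 ± 0.43, at least 1.16-fold) and Ebf1 (1.74 ± 0.14, 3.33-fold) were among the higher members. Foxc1, named after its value was seen, was the lower one (log2 −1.16 ± 0.22, adjusted p = 0.00526), and Ebf2, also named after its value was seen, did not pass (−0.24, adjusted p = 0.285). Further genes among the largest log2 values were the LIM-homeodomain gene Lhx8 (4.14 ± 0.43, at least 2.57-fold), the midbrain homeobox gene En2 (3.53 ± 0.31, at least 1.90-fold), the fore- and midbrain homeobox gene Otx2 (3.79 ± 0.73), the insulin-like growth factor binding protein relative Kazald1 (3.51 ± 0.44, at least 2.01-fold) and Ctla2a (2.90 ± 0.49, at least 1.91-fold), each with an adjusted p of at most 0.00543. Otx2, En2 and Lhx2 belong to the forebrain, midbrain and eye list, of whose 6 tested members 4 were higher and none lower (4 higher and 1 lower when adjusted over the list alone; median log2 2.60, camera adjusted p = 0.000573; adjusted p = 0.0613 with an estimated correlation). The fourth was the homeobox gene Dlx2 (1.67 ± 0.17).

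All 10 tested Hox genes of paralog groups 5 to 13 were lower in head, also when adjusted over the list alone (median log2 −3.62, camera adjusted p = 2.26e-16; adjusted p = 0.056 with an estimated correlation). All 8 tested genes of groups 1 to 4 were lower too, also when adjusted over the list alone (median −1.42, camera adjusted p = 2.6e-12; 0.00858 with an estimated correlation). The most negative log2 values included those of Hoxc4 (log2 −8.25 ± 0.35, at least 21.4-fold lower), Hoxc8 (−7.55 ± 0.43, at least 32.5-fold), Hoxa9 (−7.05 ± 0.32, at least 41.8-fold), Hoxa5 (−5.98 ± 0.34, at least 9.19-fold), Hoxb5 (−5.13 ± 0.48, at least 2.81-fold), Hoxd9 (−4.25 ± 0.45, at least 1.78-fold) and Hoxb4 (−3.88 ± 0.38, at least 2.28-fold). The secreted protein gene C1qtnf3 was at least 6.72-fold lower in head (−6.66 ± 0.39). Of 14 tested dermomyotome and limb myoblast regulators 7 were lower and 1 higher in head, or 7 and 2 when adjusted over the list alone (median −1.08, camera adjusted p = 1.1e-06; adjusted p = 0.0655 with an estimated correlation). Among the lower ones were the somite factors Meox2 (−2.08 ± 0.13, 4.22-fold), Meox1 (−2.97 ± 0.19, at least 7.29-fold), Tcf15 (−3.29 ± 0.24, at least 6.43-fold) and Dmrt2 (−4.51 ± 0.33, at least 2.91-fold), Sim1 of the lateral dermomyotome (−3.52 ± 0.22, at least 5.35-fold), and Pax3, which marks the dermomyotome (−1.46 ± 0.19, 2.76-fold). The higher one was the chemokine receptor Cxcr4, named after its value was seen (1.17 ± 0.14, 2.26-fold). In the sclerotome and tendon list 3 of 6 tested members were lower and 1 higher, also when adjusted over the list alone (median −1.04, camera adjusted p = 0.0207; adjusted p = 0.232 with an estimated correlation): Uncx (−4.06 ± 0.65), Pax1 (−2.63 ± 0.24) and Foxc2 (−1.85 ± 0.20) were lower, and Ets2 (0.61 ± 0.13) was higher.

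**Figure D1:**
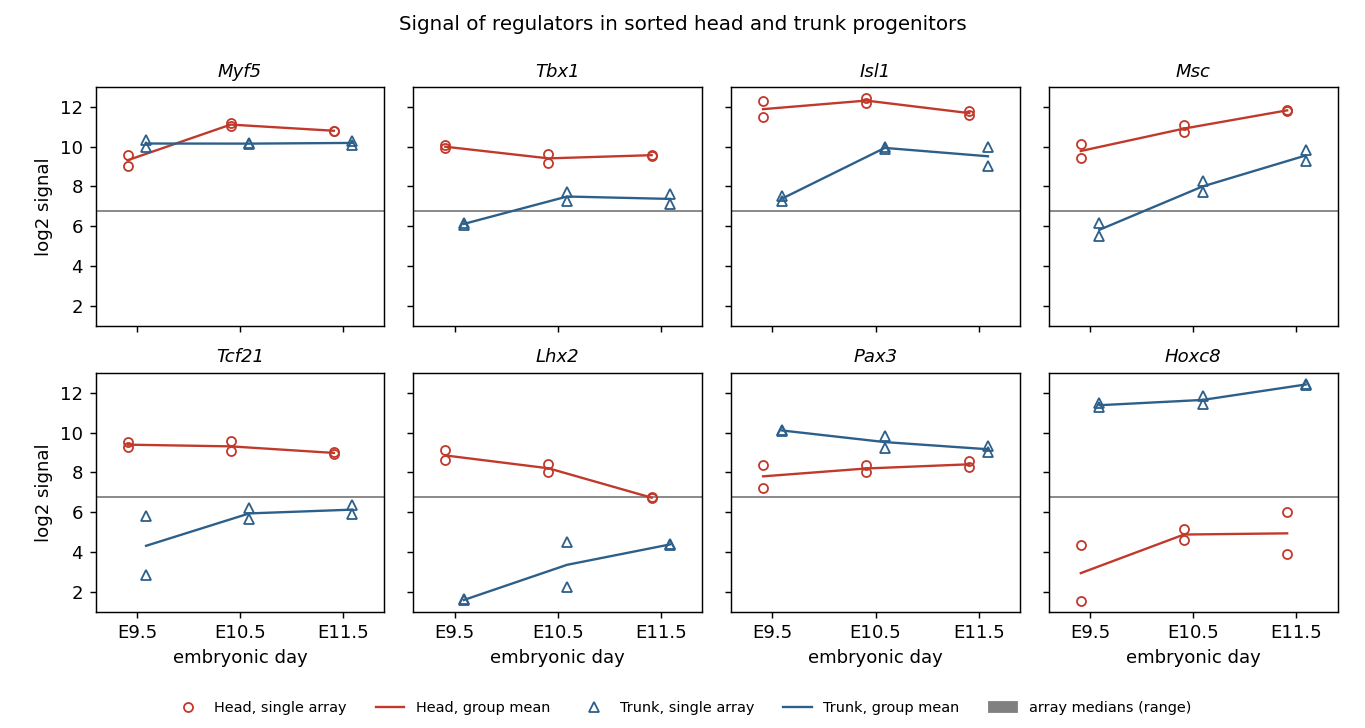
Log2 signal of 8 regulators plotted against embryonic day, with each array as a circle (head) or a triangle (trunk), lines through the group means of 2 arrays, and a grey band for the range of array medians. Tbx1, Isl1 and Msc lie above trunk at every stage in head, the Hox gene Hoxc8 lies below, and Isl1 in trunk goes from 7.38 at E9.5 to 9.51 at E11.5.

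Transcripts of several other cell types were higher in the head samples than in the trunk samples over the mean of the 3 stages. Few of them passed at E11.5, as given below. The difference does not say which cells in the samples hold these transcripts. All 14 tested endothelial genes were higher in head, also when adjusted over the list alone, with a median of log2 1.62 (camera adjusted p = 1.89e-16; adjusted p = 0.0613 with an estimated correlation). Among them were the VEGF receptor Kdr (2.18 ± 0.23, 4.52-fold) and the tight junction gene Cldn5 (1.90 ± 0.18, at least 3.59-fold). Of 17 neuronal genes 14 were higher and 1 lower, also when adjusted over the list alone (median 1.26, camera adjusted p = 5.73e-11; adjusted p = 0.117 with an estimated correlation). Neurod1, a neurogenic transcription factor, was at least 4.99-fold higher (2.41 ± 0.16), the neuronal migration gene Dcx at least 2.48-fold (1.55 ± 0.19). Neurog2, named after its value was seen, was the lower one (−1.99 ± 0.42). Of 15 epithelial genes 11 were higher and none lower, or 12 and 1 when adjusted over the list alone (median 1.18, camera adjusted p = 5.51e-10; adjusted p = 0.117 with an estimated correlation). The adhesion gene Epcam led them (1.32 ± 0.12, 2.50-fold). Of 6 macrophage and leukocyte genes 4 were higher, or 5 when adjusted over the list alone (median 0.98, camera adjusted p = 4.16e-05; adjusted p = 0.0613 with an estimated correlation). They were Laptm5 (1.93 ± 0.19), Coro1a (1.07), Adgre1 (0.90) and the macrophage receptor Csf1r (1.55 ± 0.31). Among 6 erythroid genes only Tal1 was higher (1.88 ± 0.55, adjusted p = 0.0484), or 3 genes when adjusted over the list alone (median 0.78, camera adjusted p = 0.0097; adjusted p = 0.275 with an estimated correlation). The embryonic globins Hbb-bh1 (1.02, adjusted p = 0.135) and Hbb-y (0.24, adjusted p = 0.277) did not pass, but both did without head E11.5 replicate 2 (1.51, adjusted p = 0.00103, and 0.37, adjusted p = 0.0278). Leaving out single arrays cost Tal1 its call, with an adjusted p of up to 0.119 without head E9.5 replicate 2.

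Over the mean of the 3 stages some members of other cell type lists were lower in head, although several connective tissue genes were higher at E9.5, as given below. In the connective tissue and extracellular matrix list 6 of 22 tested members were lower and 1 higher, or 9 and 2 when adjusted over the list alone (median −0.33, camera adjusted p = 0.00155; adjusted p = 0.275 with an estimated correlation). The Notch ligand relative Dlk1 (−1.89 ± 0.22, at least 3.49-fold) and the growth factor receptor Pdgfra (−1.23 ± 0.16, 2.34-fold) were among the lower ones. The higher one, Sparc (0.61), was named after its value was seen. Of 8 neural progenitor genes 3 were lower, or 4 when adjusted over the list alone (median −0.54, camera adjusted p = 0.00472; adjusted p = 0.0691 with an estimated correlation). They were Zic1 (−2.88 ± 0.25, 7.35-fold), Hes5 (−1.65 ± 0.40) and Pax6 (−1.22 ± 0.35). Zic1 is also in the dermomyotome list, so its difference does not point to neural progenitors alone. Muscle genes went both ways. Of 24 skeletal muscle differentiation genes 7 were lower in head and 1 higher, or 9 and 1 when adjusted over the list alone (median −0.42, camera adjusted p = 0.0034; adjusted p = 0.31 with an estimated correlation). The lower ones included slow troponin I Tnni1 (−1.72 ± 0.31, at least 1.38-fold) and skeletal actin Acta1 (−1.65 ± 0.30, at least 2.72-fold). Tropomyosin Tpm2 was the higher one (0.82 ± 0.11), a call that ended when probe sets with the suffixes _s, _x and _a were left out (adjusted p = 0.85). Among 10 myogenic regulatory factors and cofactors Myog was lower (−1.01 ± 0.21) and Mef2d higher (0.60 ± 0.12), also when adjusted over the list alone (median 0.22, camera adjusted p = 0.21). For Myog this mean does not hold at each stage. It was −2.37 at E9.5 and −1.23 at E10.5 (adjusted p = 0.0729 by limma), and its change to E11.5 was higher in head by 2.95. No myogenic factor passed at E11.5, where Myod1 had the smallest p (1.13, adjusted p = 0.0954). Of 6 cardiac progenitor regulators Isl1 and Nkx2-5 (1.91 ± 0.30, at least 1.48-fold) were higher, or 3 genes when adjusted over the list alone (median 0.49, camera adjusted p = 0.00525; adjusted p = 0.128 with an estimated correlation). Of 6 cardiac contractile genes Tnni1 and Tnnt2 (−1.17 ± 0.29) were lower, or 3 genes when adjusted over the list alone (median −0.78, camera adjusted p = 0.0335; adjusted p = 0.243 with an estimated correlation). Leaving out single arrays cost Tnnt2, Hes5, Sparc and Pax6 their calls. Pax6 had the highest adjusted p, 0.127 without trunk E10.5 replicate 2.

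**Figure D2:**
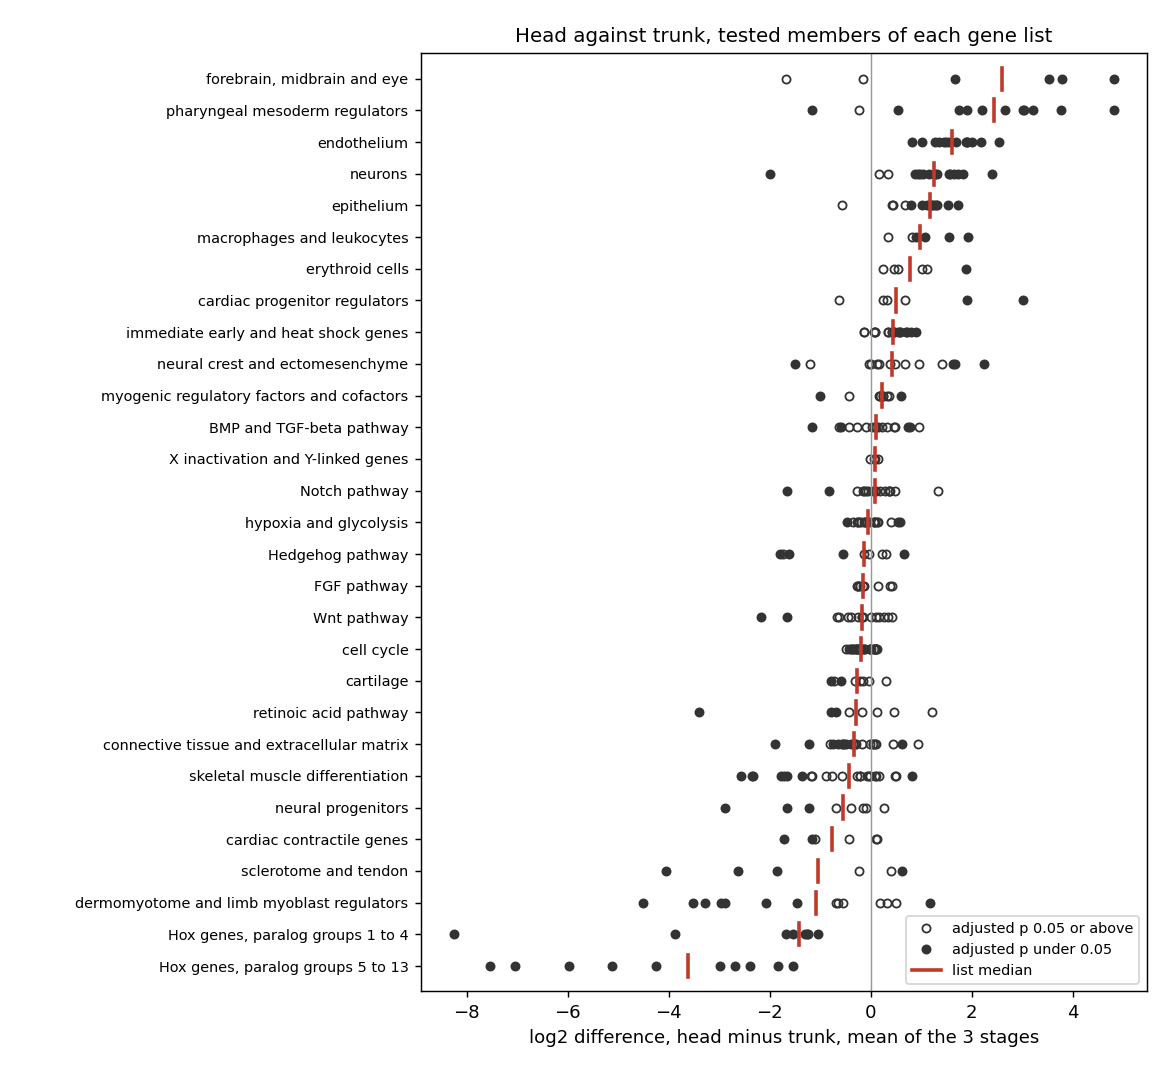
Log2 difference between head and trunk, averaged over the 3 stages, for each tested member of the 29 gene lists sorted by their median; filled points passed at an adjusted p under 0.05, open points did not, and the red bar is the list median. Medians run from −3.62 for the Hox genes of groups 5 to 13 to 2.60 for the forebrain, midbrain and eye genes, with endothelium at 1.62.

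At E9.5 pharyngeal regulators, neuronal and endothelial transcripts were among those higher in head, and Hox and dermomyotome genes among those lower. Lhx2 was at least 4.23-fold higher in head (log2 7.26, adjusted p = 5.98e-05), Tbx1 at least 9.31-fold (3.87 ± 0.24, adjusted p = 3.53e-06), Isl1 22.5-fold (4.49 ± 0.30, adjusted p = 6.05e-06), Msc at least 8.03-fold (3.95) and Tcf21 at least 6.15-fold (5.08). Otx2 (6.44), Tlx1 (5.44) and Kazald1 (4.85) were also among the largest log2 values. Hoxc4 (−8.98, at least 18.8-fold lower), Hoxc8 (−8.42), Dmrt2 (−7.35, at least 4.91-fold), Hoxa9 (−7.08) and Hoxa5 (−6.27) had the most negative log2 values. Myf5 was lower in head (−0.84, adjusted p = 0.0308), as were Pax3 (−2.30, 4.93-fold) and Myog, which drives terminal differentiation (−2.37). Of the pharyngeal regulators 10 were higher, or 11 higher and 1 lower when adjusted over the list alone (median 3.15, camera adjusted p = 9e-17; 0.00394 with an estimated correlation). Of the dermomyotome regulators 8 were lower, or 8 lower and 2 higher when adjusted over the list alone (median −2.23, camera adjusted p = 9.92e-10; 0.0396 with an estimated correlation). Of the 17 neuronal genes 14 were higher, or 15 when adjusted over the list alone (median 2.10, camera adjusted p = 9e-17; adjusted p = 0.0648 with an estimated correlation). Neurod1 was at least 22.2-fold (4.75 ± 0.29) and Dcx at least 9.68-fold higher (4.0). Of the endothelial genes 10 were higher, or 12 when adjusted over the list alone (median 2.05, camera adjusted p = 1.34e-13; adjusted p = 0.0648 with an estimated correlation), Kdr by 8.94-fold. Of 15 epithelial genes 7 were higher, or 9 higher and 1 lower when adjusted over the list alone (median 1.3, camera adjusted p = 3.9e-07; adjusted p = 0.181 with an estimated correlation). They included Epcam (1.96), Spint2 (1.67), Esrp1 (2.16) and Krt8 (1.3). Of 22 connective tissue genes 6 were higher and 2 lower at this stage, also when adjusted over the list alone (median 0.32, camera adjusted p = 0.0434; adjusted p = 0.566 with an estimated correlation). The higher ones included Sparc (1.71), Lum (2.02), Tnc (2.16, with both tissues below the median probe set) and Postn (0.97). Of the 24 muscle differentiation genes 4 were higher in head and none lower, also when adjusted over the list alone (median 0.26, camera adjusted p = 0.236): slow myosin Myh7 (3.46, at least 3.85-fold), Tpm2 (0.93), Myh8 (2.82) and the receptor subunit Chrnb1 (1.98). Myh8 and Chrnb1 lay below the median probe set in both tissues, so their log2 values are not measured folds. Tpm2 turned to −0.27 (adjusted p = 0.8) when probe sets with the suffixes _s, _x and _a were left out. In limma 457 genes differed, 361 of them higher in head. The count was 238 without trunk E9.5 replicate 1 and 256 without head E9.5 replicate 2. Chrnb1, Myf5, Myh8, Otx2, Tpm2, Tnc, Postn, Esrp1 and Krt8 lost their calls without single arrays. Chrnb1 had the highest adjusted p, 0.237 without head E9.5 replicate 2.

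At E10.5 muscle differentiation genes were among those lower in head. Of the 24 tested differentiation genes 9 were lower in head, or 15 lower and 1 higher when adjusted over the list alone (median log2 −1.91, camera adjusted p = 1.07e-08; adjusted p = 0.159 with an estimated correlation). They included Tnni1 (−3.31, at least 2.55-fold), the calcium release channel Ryr1 (−4.70, with both tissues below the median probe set), cardiac actin Actc1 (−1.92, 3.79-fold) and the myosin binding protein Mybph (−4.87, at least 1.3-fold). Myf5 was higher in head (0.96, adjusted p = 0.0275). Tbx1 (1.91, 3.77-fold), Isl1 (2.38, 5.19-fold), Msc (2.90, 7.49-fold) and Tcf21 (3.36, at least 5.74-fold) remained higher, and Pax3 was 2.51-fold lower (−1.33, adjusted p = 0.0434). The largest log2 values were those of Lhx2 (4.84), Lhx8 (4.55), Kazald1 (3.80), En2 (3.53) and the haematopoietic factor Runx1 (3.43, at least 3.88-fold) on the head side. On the trunk side they were those of C1qtnf3 (−7.60, at least 12.8-fold), Hoxa9 (−7.44, at least 49.3-fold), Hoxc4 (−7.36), Hoxc8 (−6.76) and Hoxa5 (−5.63). Of the endothelial genes 9 were higher in head, or all 14 when adjusted over the list alone (median 1.73, camera adjusted p = 7.96e-13; adjusted p = 0.0887 with an estimated correlation). Of the 17 neuronal genes 1 was higher, Gap43 by 1.54, or 4 genes when adjusted over the list alone (median 0.85, camera adjusted p = 0.00295; adjusted p = 0.427 with an estimated correlation). With the replicate numbers as a block by stage 213 genes differed, 116 of them higher in head. With only the groups compared in the fit 679 did. In the main limma fit 349 genes differed, 189 of them higher in head. The count was 99 without head E10.5 replicate 1, 74 without trunk E10.5 replicate 1, 64 without trunk E10.5 replicate 2, and 34 without both replicate 1 arrays, an omission chosen after the data were seen. Pax3, Actc1, Mybph, Gap43, Myf5, Kazald1, Tcf21, Ryr1, Lhx8 and Tnni1 lost their calls without single arrays. Pax3 had the highest adjusted p, 0.271 without trunk E10.5 replicate 2. Of the genes called at this stage 125 had several probe sets that passed the filter, and 36 of these had one of opposite sign.

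By E11.5 fewer genes passed between the tissues, and most of them were lower in head. Connective tissue genes stood out among these. Of 22 tested 8 were lower, or 11 when adjusted over the list alone (median log2 −0.89, camera adjusted p = 1.86e-14; adjusted p = 0.0606 with an estimated correlation). The matrix genes among them were Postn (−2.01, 4.02-fold), Lum (−2.31, 4.95-fold) and Dcn (−2.45, 5.46-fold). Of the 8 neural progenitor genes 4 were lower, also when adjusted over the list alone (median −1.23, camera adjusted p = 6.84e-06; 0.0247 with an estimated correlation). These were Zic1, which is also in the dermomyotome list (−3.68, 12.8-fold), the stem cell factor Sox2 (−1.49), the radial glia gene Fabp7 (−2.38) and Hes5 (−3.24, at least 7.25-fold). Fabp7 had been higher in head at E9.5 (2.03, adjusted p = 0.0325 by limma). The pharyngeal regulators Tbx1 (2.19, 4.56-fold), Isl1 (2.17, 4.49-fold) and Msc (2.26, 4.80-fold) were still higher in head. Six2 (2.25) was the fourth of 4 called members that were higher, or 9 higher and 2 lower when adjusted over the list alone (median 2.16, camera adjusted p = 3.7e-07; 0.0247 with an estimated correlation). Tcf21 (2.85, adjusted p = 0.0536), Lhx2 (2.34, adjusted p = 0.126), Pax3 (−0.75, adjusted p = 0.399) and Myf5 (0.61, adjusted p = 0.215) did not pass at this stage. Tcf21 passed without trunk E9.5 replicate 1 or 2 (adjusted p = 0.000818 and 0.00101), and Lhx2 without trunk E10.5 replicate 1 (0.0362). Ebf2 was the 1 called member that was lower (−1.75, 3.37-fold). The largest log2 values were those of the procollagen enhancer Pcolce2 (3.73, at least 7.46-fold), Lhx8 (3.72), En2 (3.68), Rasd2 (3.48) and Lbx1 of migrating muscle precursors (2.75, at least 4.08-fold) on the head side. On the trunk side they were those of Hoxc4 (−8.40, at least 25.2-fold), Hoxc8 (−7.47, at least 49.6-fold), C1qtnf3 (−6.77), Hoxa9 (−6.65, at least 47.6-fold) and Hoxa5 (−6.02). Of the endothelial genes Kdr (1.74), Cldn5 (1.35) and Sox17 (2.01) were higher in head, or 9 genes when adjusted over the list alone (median 1.07, camera adjusted p = 4.15e-11; adjusted p = 0.0771 with an estimated correlation). Only Neurod1 of the neuronal genes was called (1.41, adjusted p = 0.0283 by limma). No epithelial or leukocyte gene passed at this stage. Their smallest p-values were those of Epcam (0.67, adjusted p = 0.145) and Laptm5 (1.39, adjusted p = 0.0552). In limma 160 genes differed, 55 of them higher in head. The count was 72 and 62 without head E11.5 replicate 1 and 2, 56 and 61 without trunk E11.5 replicate 1 and 2, and 104 and 103 without trunk E10.5 replicate 1 and 2. Sox17, Kdr, Cldn5, Rasd2, Lbx1, Hes5, Fabp7, Lhx8, Dcn, Sox2, Lum and En2 lost their calls without single arrays. Sox17 had the highest adjusted p, 0.315 without trunk E11.5 replicate 2, where the log2 value of Kdr was 1.1.

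The second question was how head progenitors changed from E9.5 to E11.5. Muscle genes were among those that rose and epithelial genes among those that fell. Myod1 and Myog, the myogenic factors of commitment and differentiation, rose at least 20.4-fold (log2 4.92 ± 0.30, n = 2 arrays per stage, adjusted p = 6.91e-06 by limma) and at least 13.1-fold (5.50 ± 0.36, adjusted p = 8.7e-06). Myf5 rose 2.80-fold (1.48 ± 0.21, adjusted p = 0.00165) and Msc 4.11-fold (2.04 ± 0.31). Fitted log2 values of genes below the median probe set are not measured folds. Embryonic myosin Myh3 (8.87 ± 1.14, at least 18.2-fold) and slow troponin T Tnnt1 (6.38 ± 0.71, at least 13.2-fold) had the largest fitted log2 values. Next to them stood Mybph (4.93), Ryr1 (4.76), Chrna1, a subunit of the acetylcholine receptor of muscle (4.5), the matrix gene Ogn (4.93 ± 0.57), Lbx1 (4.67 ± 0.62, at least 4.07-fold) and the synuclein Sncg (4.57). Of 24 skeletal muscle differentiation genes 18 rose, or 19 when adjusted over the list alone (median 2.50, camera adjusted p = 8.43e-18; adjusted p = 0.161 with an estimated correlation). Of the 10 myogenic factors 4 rose, or 6 when adjusted over the list alone (median 0.88, camera adjusted p = 3.38e-09; 0.0174 with an estimated correlation). The fourth was the cadherin Cdh15 (2.60). In the dermomyotome list 5 of 14 rose, or 6 when adjusted over the list alone (median 0.83, camera adjusted p = 0.000441; adjusted p = 0.177 with an estimated correlation). Meox2 (1.68, 3.20-fold), Lbx1, Dmrt2 (3.60) and Cxcr4 (1.05) were 4 of them, and the fifth, Meox1 (1.38, adjusted p = 0.0321), was named after its value was seen. Pax3 (0.60, adjusted p = 0.388), Isl1 (−0.20, adjusted p = 0.806), Tbx1 (−0.43, adjusted p = 0.398), Tcf21 (−0.42, adjusted p = 0.815) and Lhx2 (−2.12, adjusted p = 0.109) did not pass, except Lhx2 without trunk E10.5 replicate 1 or 2 (adjusted p = 0.0295 and 0.0447). In the pharyngeal list Msc rose and Ebf2 fell (−1.25), and 3 genes rose and 3 fell when adjusted over the list alone (median −0.31, camera adjusted p = 0.615). Of the genes named here Mybph, Meox1, Cxcr4, Sncg, Ebf2, Chrna1 and Ryr1 lost their calls without single arrays. Mybph had the highest adjusted p, 0.237 without head E11.5 replicate 1.

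Epithelial genes were among those that fell in head over the same period, while the neural lists went both ways. Of 15 epithelial genes 9 fell, or 11 when adjusted over the list alone (median log2 −1.69, camera adjusted p = 3.77e-12; adjusted p = 0.177 with an estimated correlation). Among them were the keratins Krt8 (−3.54 ± 0.30, at least 10.4-fold) and Krt18 (−2.90, at least 6.25-fold) and Epcam (−2.20, 4.58-fold). Lin28a, which blocks maturation of let-7 microRNAs in early embryos, fell at least 3.52-fold (−3.55), and the glucose transporter Slc2a3 fell 7.92-fold (−2.99). Otx2 (−5.78, at least 3.54-fold), the neurogenic factor Neurog1 (−4.01, at least 3.27-fold) and the Notch target Hes5 (−3.37, at least 7.92-fold) fell. So did the growth factor binding protein Wfikkn1 (−5.47, at least 1.14-fold), the endocytic receptor Lrp2 (−4.38), Qprt (−3.84), the matrix link protein Hapln1 (−3.68 ± 0.31, at least 6.34-fold) and Igdcc3 (−3.36). In the hypoxia and glycolysis list Slc2a3, Slc2a1 (−1.16), Pdk1 (−1.55) and, named after their values were seen, Pfkl (−1.18) and P4ha1 (−0.90) fell and Egln3 (0.99) rose. These were 5 and 1 of 18, or 8 and 2 when adjusted over the list alone (median −0.22, camera adjusted p = 0.0116; adjusted p = 0.177 with an estimated correlation). Of 8 neural progenitor genes 2 fell, Sox2 (−2.33, 5.02-fold) and Hes5, and Nes rose (1.12), also when adjusted over the list alone (median −0.98, camera adjusted p = 0.0073; adjusted p = 0.172 with an estimated correlation). In the neuronal list Neurod1 (−1.98, 3.94-fold) and Neurog1 fell and Stmn3 rose (2.34), or 3 fell and 8 rose when adjusted over the list alone (median 0.59, camera adjusted p = 0.0931). In limma 369 genes changed, 212 rising and 157 falling. The count was 173 without head E9.5 replicate 1, 226 without head E11.5 replicate 1 and 194 without head E11.5 replicate 2. Here P4ha1, Otx2, Pfkl, Stmn3, Nes, Pdk1, Hes5, Wfikkn1, Lrp2, Egln3, Slc2a1 and Neurog1 lost their calls without single arrays. P4ha1 had the highest adjusted p, 0.171 without head E11.5 replicate 1. The log2 value of Stmn3 was 1.33 without head E9.5 replicate 1.

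The same question in the trunk gave more changed genes, with muscle, connective tissue and neuronal genes among those that rose from E9.5 to E11.5. Myod1 rose at least 9.39-fold (log2 3.84, n = 2 arrays per stage, adjusted p = 1.34e-05 by limma), Myog 5.84-fold (2.55) and the muscle cofactor Mef2c 5.16-fold (2.37). Myf5 did not pass (0.03, adjusted p = 0.953). Of 24 skeletal muscle differentiation genes 22 rose, or 23 when adjusted over the list alone (median 3.19, camera adjusted p = 1.01e-18; adjusted p = 0.103 with an estimated correlation). Myh3 (6.13, at least 18.3-fold), Tnnt1 (6.06, at least 11-fold), Ryr1 (5.93), Chrna1 (4.97) and titin Ttn (4.15, at least 13.8-fold) were among them. Without trunk E9.5 replicate 1 the log2 value of Myh3 was 3.49. The largest fitted log2 value, which for genes below the median probe set is not a measured fold, was that of Bcl11b, a zinc finger transcription factor (7.15 ± 0.38, at least 6.35-fold, adjusted p = 1.05e-06), followed by the angiotensin receptor Agtr2 (6.84, at least 5.30-fold). Ogn (6.18), the adhesion molecule Vcam1 (5.25 ± 0.54, at least 9.33-fold), the cartilage collagen Col9a3 (5.03) and the protease Corin (4.97, at least 10.2-fold) were also among the 10 largest values. Of 22 connective tissue genes 14 rose, or 15 when adjusted over the list alone (median 1.28, camera adjusted p = 5.77e-12; adjusted p = 0.143 with an estimated correlation). Postn rose by 10.8-fold (3.44 ± 0.24), tenascin C Tnc at least 4.22-fold (4.54) and the matrix protein Sparc 5.34-fold (2.42). Of 17 neuronal genes 11 rose, or 14 when adjusted over the list alone (median 1.90, camera adjusted p = 1.37e-10; adjusted p = 0.186 with an estimated correlation). Dcx (4.75 ± 0.33, at least 16.2-fold) and the neurofilament gene Nefm (4.02, at least 12.2-fold) were in front. Without single arrays Col9a3 lost its call, with an adjusted p of up to 0.137 without trunk E11.5 replicate 2.

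Several regulators that were higher in head at E9.5 rose in trunk. Neuronal genes rose in the same samples, and which cells hold the regulator transcripts was not tested. Of 12 pharyngeal mesoderm regulators 7 rose in trunk, or 8 when adjusted over the list alone (median log2 1.46, camera adjusted p = 1.38e-06; adjusted p = 0.0919 with an estimated correlation). They rose by different amounts, Msc at least 6.88-fold (3.73 ± 0.31, adjusted p = 1.92e-05), Isl1 4.38-fold (2.13 ± 0.30), Ebf2 4.13-fold (2.05), Ebf1 3.02-fold (1.59) and Tbx1 at least 1.52-fold (1.26 ± 0.24) among them. Lhx2 rose by log2 2.79, with both stages below the median probe set. Tcf21 did not pass (1.82, adjusted p = 0.1), and neither did Pax3 (−0.94, adjusted p = 0.0865). Tcf21 passed without trunk E9.5 replicate 2 (3.29, adjusted p = 0.000262), and Pax3 without head E9.5 replicate 1 or 2 (adjusted p = 0.0263 and 0.0259). In the dermomyotome list Meox1 fell 3.89-fold (−1.96), also when adjusted over the list alone, and no other member passed (median −0.49, camera adjusted p = 0.22). The most negative log2 values were those of Wfikkn1 (−6.02, at least 1.82-fold), Lin28a (−4.36, at least 4.39-fold), the arginase Arg1 (−3.81, at least 11.6-fold), Sall4, a zinc finger factor of pluripotent cells (−3.65 ± 0.26, 12.5-fold), Igsf5 (−3.51), the homeobox gene Nkx1-2 (−3.41, at least 2.83-fold), Lrp2 (−3.16), the activin binding protein Fst (−2.84, 7.17-fold), ceruloplasmin Cp (−2.79, at least 4.67-fold) and desmoplakin Dsp (−2.64, 6.25-fold). Of 15 epithelial genes 6 fell, or 12 when adjusted over the list alone (median −1.32, camera adjusted p = 5.59e-07; adjusted p = 0.19 with an estimated correlation), Krt8 at least 4.36-fold (−2.40). In the hypoxia and glycolysis list 8 of 18 fell, or 10 fell and 1 rose when adjusted over the list alone (median −0.64, camera adjusted p = 0.000472; adjusted p = 0.112 with an estimated correlation). They included Slc2a3 (−1.87, 3.66-fold) and lactate dehydrogenase Ldha (−1.02, 2.02-fold). Of 29 cell cycle genes 5 fell, or 8 when adjusted over the list alone (median −0.32, camera adjusted p = 0.000462; adjusted p = 0.186 with an estimated correlation). These were ribonucleotide reductase Rrm2 (−0.52, 1.43-fold), the mitotic kinase Plk1 (−1.24, 2.35-fold), the replication factors Mcm3 (−0.69) and Pcna (−0.66) and, named after its value was seen, Mcm5 (−0.93). In limma 1038 genes changed, 674 rising and 364 falling. The count was 434 without trunk E9.5 replicate 1, 581 without trunk E11.5 replicate 1 and 460 without trunk E11.5 replicate 2. Mcm5, Pcna, Lrp2, Mcm3, Igsf5, Plk1, Lhx2, Arg1, Ldha and Tbx1 lost their calls without single arrays. Mcm5 had the highest adjusted p, 0.308 without trunk E11.5 replicate 2, where its log2 value was −0.61.

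The single steps of 1 day show Myf5 rising in head before E10.5 and many more calls in trunk before E10.5 than after it, a difference between the steps that was not tested itself. From E9.5 to E10.5 in head Myf5 rose 3.47-fold (log2 1.79 ± 0.21, n = 2 arrays per stage, adjusted p = 0.00266 by limma), Myog at least 2.51-fold (3.11) and Myod1 at least 2.38-fold (1.82). That made 3 of the 10 myogenic factors, or 4 when adjusted over the list alone (camera adjusted p = 0.000597; adjusted p = 0.182 with an estimated correlation). Myh3 (5.51), Tnnt1 (4.51, at least 3.60-fold), Ogn (3.44), Lbx1 (3.41) and Bcl11b (3.16, at least 3.69-fold) had the largest log2 values. Slc2a3 (−2.65, 6.29-fold), the guidance ligand Slit3 (−2.59), the phospholipase Plcg2 (−1.73), plakophilin Pkp2 (−1.54, 2.91-fold) and Sall4 (−1.50, 2.83-fold) had the most negative ones. In all 54 genes rose and 20 fell. This count of 74 was 13 and 114 without head E9.5 replicate 1 and 2, 2 and 135 without head E10.5 replicate 1 and 2, 35 and 34 without trunk E10.5 replicate 1 and 2, 46 and 45 without trunk E11.5 replicate 1 and 2, and 0 without both E10.5 replicate 1 arrays, an omission chosen after the data were seen. Each of the 13 genes named for this step lost its call without single arrays. Plcg2 had the highest adjusted p, 0.265 without head E9.5 replicate 1. From E10.5 to E11.5 in head 41 genes rose and 35 fell, Myod1 by 8.56-fold (3.10 ± 0.30, adjusted p = 0.00119) and Myog by 5.23-fold (2.39). Ryr1 (5.92), the sarcomeric actinin Actn2 (3.82, at least 4.82-fold), the potassium channel subunit Kcne4 (3.30) and Aar2 (3.29, at least 4.90-fold) were the others among the largest log2 values. Igdcc3 (−2.83), Hapln1 (−2.19), Krt8 (−2.11, at least 3.86-fold), Clec1b (−1.95) and Colec12 (−1.89, at least 3.67-fold) had the most negative ones. This count of 76 was 6 and 165 without head E10.5 replicate 1 and 2, 18 and 6 without head E11.5 replicate 1 and 2, 26 and 25 without trunk E10.5 replicate 1 and 2, and 4 without both E10.5 replicate 1 arrays. Of the genes named for the second step all but Myod1 lost their calls without single arrays. Actn2 had the highest adjusted p, 0.231 without head E10.5 replicate 1.

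In trunk 556 genes changed from E9.5 to E10.5, 422 rising and 134 falling, with muscle, neuronal and pharyngeal transcripts among those that rose. Bcl11b (log2 6.50, at least 4.07-fold), Myh3 (5.61, at least 12.8-fold), Agtr2 (5.17), Ryr1 (5.13) and Dcx (4.59, at least 14.6-fold) had the largest fitted log2 values. For genes below the median probe set these are not measured folds. The pharyngeal regulators Isl1 (2.55, 5.86-fold), Msc (2.17, at least 2.34-fold) and Tbx1 (1.37, at least 1.65-fold) rose in this step. Of the pharyngeal list 6 of 12 rose, or 8 when adjusted over the list alone (median 1.34, camera adjusted p = 1.07e-05; adjusted p = 0.135 with an estimated correlation). Of the neuronal list 13 of 17 rose, or 14 when adjusted over the list alone (median 2.24, camera adjusted p = 9.31e-14; adjusted p = 0.214 with an estimated correlation). AI506816 (−4.28, at least 4.94-fold), Lin28a (−3.59, at least 4.37-fold), Nkx1-2 (−3.33), Dsp (−2.54, 5.82-fold) and the interferon-induced membrane protein Ifitm1 (−2.46, at least 4.85-fold) had the most negative ones. The count of 556 was 159 without trunk E9.5 replicate 1, 105 and 233 without trunk E10.5 replicate 1 and 2, and 94 without both E10.5 replicate 1 arrays. Myh3, whose log2 value was 2.98 without trunk E9.5 replicate 1, lost its call without single arrays, as did Tbx1 and Ryr1. Myh3 had the highest adjusted p, 0.116 without trunk E10.5 replicate 1. From E10.5 to E11.5 in trunk 23 genes passed with array weights. In the main fit limma called 2 genes, 1 of them on chromosome X or Y, with 601 at an unadjusted p under 0.05. Xist was low on trunk E10.5 replicate 1. The kinase Nrk rose 3.52-fold (1.82 ± 0.20, adjusted p = 0.0067) and Postn 3.5-fold (1.81 ± 0.24, adjusted p = 0.0296). Thus 100% of the calls were higher, against 66.7% of 3 calls after quantile normalization. This count was 0 without trunk E10.5 replicate 2, without trunk E11.5 replicate 2 and without both E10.5 replicate 1 arrays, 1 without trunk E9.5 replicate 1, trunk E9.5 replicate 2 or trunk E11.5 replicate 1, and 4 without head E11.5 replicate 1 or 2. Both genes lost their calls (adjusted p = 0.218 without trunk E10.5 replicate 2).

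The last question was where the change from E9.5 to E11.5 differed between head and trunk. The change of 4 dermomyotome regulators was higher in head than in trunk, and that of 4 pharyngeal regulators was higher in trunk. Lbx1 went from a mean log2 signal of 4.14 to 8.81 in head and from 6.63 to 6.06 in trunk (difference in change 5.24 ± 0.88, n = 2 arrays per group, adjusted p = 0.012 by limma). Meox1 went from 6.56 to 7.94 in head and from 11.17 to 9.21 in trunk (3.34 ± 0.46, adjusted p = 0.00416). Dmrt2 (4.98 ± 0.81) and Meox2 (2.24 ± 0.31) were the other dermomyotome regulators called, 4 of 14 in all, or 8 higher and 1 lower when adjusted over the list alone (median 1.16, camera adjusted p = 1.49e-05; adjusted p = 0.117 with an estimated correlation). Of 12 pharyngeal regulators 4 had a lower change in head, or 9 when adjusted over the list alone (median −1.69, camera adjusted p = 3.07e-08; 0.0463 with an estimated correlation). Isl1 went from 11.88 to 11.68 in head and from 7.38 to 9.51 in trunk (−2.33 ± 0.43, adjusted p = 0.0199), Tbx1 from 9.99 to 9.57 and from 6.12 to 7.38 (−1.68 ± 0.34, adjusted p = 0.031). Ebf2 went from 10.69 to 9.44 and from 9.15 to 11.20 (−3.30 ± 0.31, adjusted p = 0.000401), and Lhx2 (−4.91 ± 0.96) was the fourth. Msc (−1.69, adjusted p = 0.0959), Tcf21 (−2.23, adjusted p = 0.354) and Pax3 (1.55, adjusted p = 0.155) did not pass. Tcf21 did without trunk E9.5 replicate 2 (−3.70, adjusted p = 0.00302), and Pax3 without head E9.5 replicate 1 (2.12, adjusted p = 0.0259). Myf5 (1.45 ± 0.29, adjusted p = 0.0307) and Myog (2.95 ± 0.51, adjusted p = 0.0133) changed more towards higher values in head. They were 2 of 10 myogenic factors called, or 3 higher and 1 lower when adjusted over the list alone (median 0.83, camera adjusted p = 0.0113; adjusted p = 0.117 with an estimated correlation). With each signal below its array's median raised to that median, the difference was 2.25 for Lbx1, 3.03 for Meox1, 1.38 for Dmrt2, 1.17 for Myog, −1.03 for Tbx1 and −2.08 for Lhx2, and these values were not tested. Tbx1, Lhx2, Myf5, Isl1, Myog, Lbx1 and Dmrt2 lost their calls without single arrays. Tbx1 had the highest adjusted p, 0.132 without trunk E11.5 replicate 2.

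Several connective tissue and neuronal genes had a higher change in trunk than in head. Of 22 connective tissue genes 5 differed in this direction, or 10 when adjusted over the list alone (median log2 −1.22, camera adjusted p = 3.77e-11; adjusted p = 0.117 with an estimated correlation). They were Postn (−2.98), Lum (−4.33 ± 0.52), Tnc (−4.09 ± 0.60), Sparc (−2.28) and, named after its value was seen, Dcn (−3.26). Of 17 neuronal genes 4 did, or 10 when adjusted over the list alone (median −1.51, camera adjusted p = 8.12e-10; adjusted p = 0.122 with an estimated correlation). They were Neurog1 (−6.18 ± 1.08), Dcx, which went from 6.04 to 10.79 in trunk and from 10.05 to 11.17 in head (−3.63), Neurod1 (−3.34) and Elavl3 (−1.93). Hoxd1 went from 4.98 to 7.74 in head and from 8.89 to 7.64 in trunk (4.02 ± 0.42). The fibroblast protease Fap (3.46 ± 0.33), Pcolce2 (3.31 ± 0.37), Fst (2.90 ± 0.59) and the secreted glycoprotein Stc2 (2.45 ± 0.47) also shifted towards head. Prr15 (−5.17 ± 1.13), Corin (−5.05 ± 0.67), slow myosin Myh7 (−4.73 ± 0.70), Vcam1 (−4.65 ± 0.77), Fabp7 (−4.40 ± 0.71) and Cdhr1 (−4.07 ± 0.65) shifted towards trunk. With signals below the array median raised to it, the untested differences were 2.21 for Hoxd1, 2.44 for Fap, 2.49 for Pcolce2, 1.76 for Stc2, −1.93 for Tnc, −2.58 for Dcn, −1.74 for Neurog1, −2.90 for Dcx, −3.06 for Neurod1 and −1.56 for Elavl3. On the same footing they were −0.60 for Prr15, −3.27 for Corin, −3.22 for Myh7, −2.62 for Vcam1, −3.95 for Fabp7 and −1.26 for Cdhr1. Of the 24 skeletal muscle differentiation genes 18 rose in head and 22 in trunk, and Myh7 alone differed in its change, also when adjusted over the list alone (median −0.39, camera adjusted p = 0.0296; adjusted p = 0.498 with an estimated correlation). With the replicate numbers as a block by stage 69 genes differed in their change, 9 with a higher and 60 with a lower change in head. In the main limma fit 114 genes did, 21 with a higher and 93 with a lower change in head, with 943 at an unadjusted p under 0.05. This count was 57 without trunk E9.5 replicate 1, 69 and 64 without trunk E11.5 replicate 1 and 2, 61 without head E9.5 replicate 2, 60 without head E11.5 replicate 2, and 63 without both E10.5 replicate 1 arrays, an omission chosen after the data were seen. Prr15, Elavl3, Fst, Stc2, Dcn, Neurog1, Vcam1 and Cdhr1 lost their calls without single arrays. Prr15 had the highest adjusted p, 0.178 without head E9.5 replicate 2. Across genes the changes in head and in trunk, which share no arrays, correlated with Pearson r = 0.56 and Spearman rho = 0.43. Of the called genes 161 rose in both tissues, where 18.5 would be shared if the calls were independent, 71 fell in both, where 7.4 would be, and 11 went opposite ways.

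**Figure D3:**
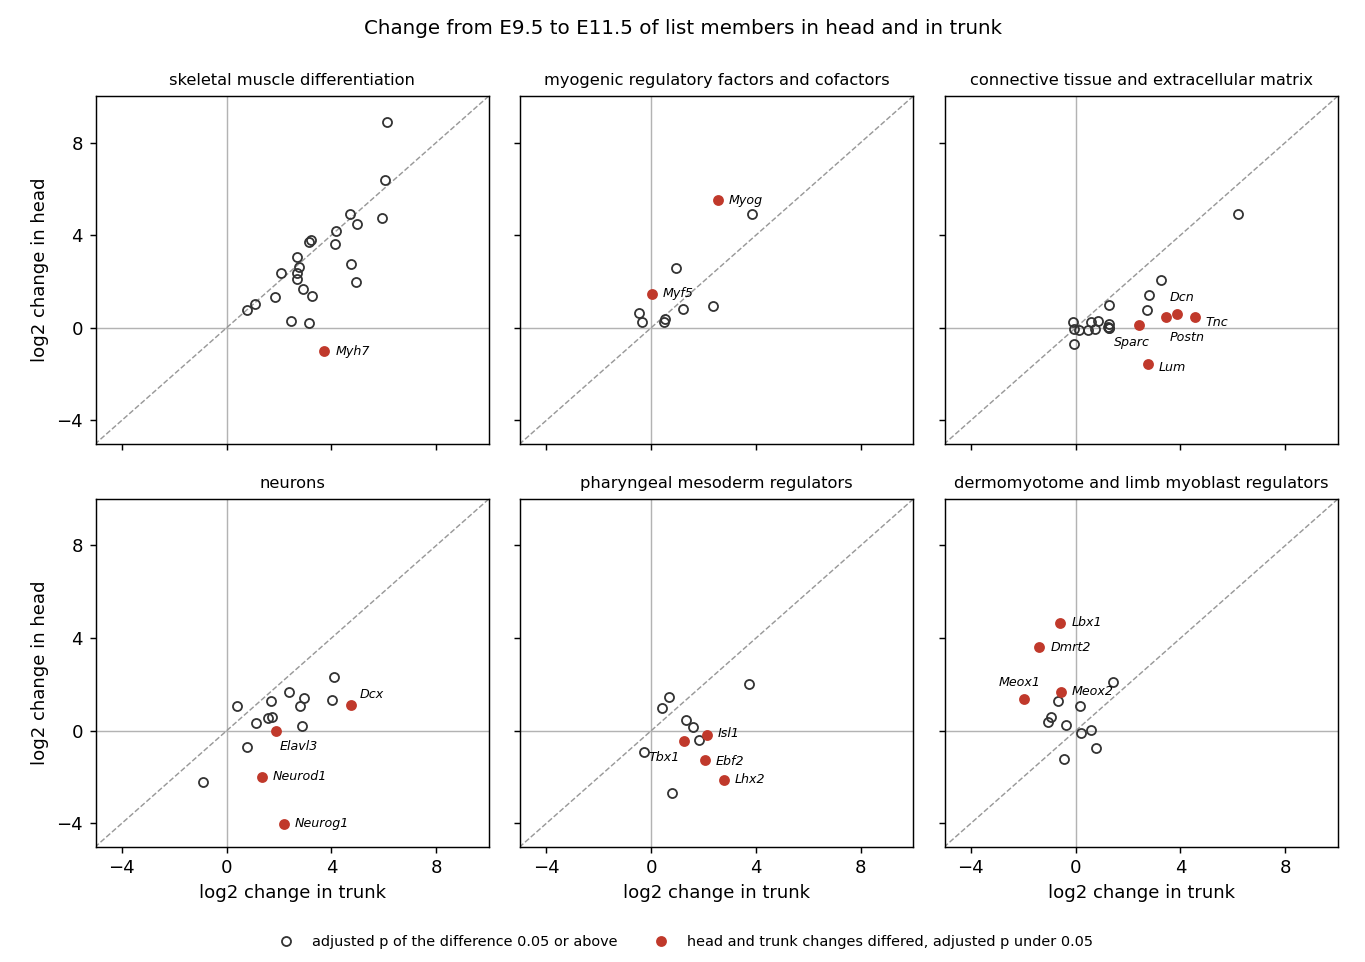
Log2 change from E9.5 to E11.5 in trunk (horizontal axis) against that in head (vertical axis) for the tested members of 6 gene lists; red filled points are genes whose change differed between the tissues at an adjusted p under 0.05, and the dashed line marks equal change. The medians of the muscle differentiation genes are 2.50 in head and 3.19 in trunk, with Myh7 at −1.01 in head and 3.73 in trunk, while Dcx at 4.75 in trunk and Lbx1 at 4.67 in head lie far from it.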

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

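The tests of other cell types in varying amounts, of a lower share of myogenic cells, of 1 deviant trunk array and of samples from male embryos only were chosen only after the result was seen, whereas the tests of noise between head arrays, of the Xist probe set and of other splits of the arrays were written before.

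In 114 genes the change from E9.5 to E11.5 differed between head and trunk by limma's test of that difference, and so did the change of each gene that follows. These are fitted values, and those of dim genes are smaller with signals below the array median raised to it, 2.25 for Lbx1, 1.38 for Dmrt2 and −0.60 for Prr15, for example. The change was higher in head for Lbx1 (log2 5.24), Dmrt2 (4.98), Hoxd1 (4.02), Fap (3.46), Meox1 (3.34), Pcolce2 (3.31), Myog (2.95), Fst (2.90), Stc2 (2.45), Meox2 (2.24) and Myf5 (1.45). It was lower in head for Tbx1 (−1.68), Isl1 (−2.33), Cdhr1 (−4.07), Tnc (−4.09), Lum (−4.33), Fabp7 (−4.40), Vcam1 (−4.65), Myh7 (−4.73), Lhx2 (−4.91), Corin (−5.05), Prr15 (−5.17) and Neurog1 (−6.18).

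Over the mean of the 3 stages, transcripts of endothelial, neuronal, epithelial and leukocyte cells were higher in head arrays. Kdr had a mean log2 signal of 9.79 in head and 7.61 in trunk, Nefm 11.01 and 9.37, Spint2 9.61 and 8.40 and Csf1r 8.94 and 7.39. Of these lists 0 members were held by another list. At E11.5 alone no epithelial or leukocyte gene passed, and of the neuronal genes only Neurod1 did. A lower share of myogenic cells in the head samples was tested only in a form that raises all other cell types alike. An uneven mix of other cell types would spread the list medians too, so the test cannot decide on a lower share with such a mix. In the tested form the medians of 7 lists spread by 2.15 at E10.5 and 2.03 at E11.5, beyond limits of 1.25 and 1.16. Each limit was 4 times the largest standard error of a list mean, taken over its genes. Members of several lists deviated together, as given below, so the limits can be too small. The test therefore does not decide on a lower share at these stages. Myf5 was not lower in head at E10.5 and E11.5 (0.96 and 0.61). At E10.5, though, Myog (−1.23, adjusted p = 0.0729 by limma) and the muscle differentiation list, with a median of −1.91 and 9 of 24 genes lower, go with a lower share. At E9.5 a lower share remains open as well, since the spread of 1.78 lay within the limit of 1.91, all 7 medians were positive and Myf5 was lower in head (−0.84, adjusted p = 0.0308, but 0.228 without head E9.5 replicate 1). Other cell types in the sorted samples, in amounts that varied between arrays, remain a candidate explanation that the tables cannot decide, although the fluorescence sort should remove cells without the label: members of 3 of the 4 lists deviated together between the arrays of a group more than the 95th percentile of 10000 random lists (mean correlation 0.41 for endothelium, 0.44 for neurons and 0.43 for epithelium), the leukocyte list did not (0.12), and lists outside these 4 did so as well, those of erythroid cells (0.57), connective tissue (0.30), muscle differentiation (0.29) and dermomyotome regulators (0.13). A difference between head and trunk in what the labelled cells themselves express remains open and was not tested.

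More genes changed between E9.5 and E11.5 in trunk than in head, 1038 against 369. Larger noise between the head arrays was argued against: after subtraction of the noise between arrays (0.36 in head, 0.34 in trunk) the standard deviation of the change across genes was 0.53 in head and 0.69 in trunk, a ratio of 1.31, which lay between 1.17 and 1.44 when each of 8 arrays was left out. One deviant array among the trunk arrays was argued against too, since the lowest trunk count with 1 of its own arrays left out was 434, above the 173 to 325 genes found in head in the same way. A larger change of the labelled trunk cells, or of the mix of cells that the trunk samples hold, may lie behind it, and neither was tested.

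The Xist signal was low on both E10.5 replicate 1 arrays, log2 7.35 in head and 6.37 in trunk against at least 11.89 elsewhere. A failure of the Xist probe set that represents the gene was argued against, because on 2 of 2 other Xist probe sets the same arrays were the lowest. The brighter of these had 1.97 in head and 4.14 in trunk, against 10.72 to 12.56 elsewhere. Only male embryos in both samples could give this pattern, but the tables do not decide: 1 of 4 Y-linked probe sets with a signal, that of Eif2s3y, had its highest values there (9.94 and 9.75), while for Uty 2 other arrays (7.45 and 7.47) lay above both (7.35 and 7.39) by less than the noise between arrays given above, its second probe set had 6.11 on the head array against up to 7.52 elsewhere, and for Kdm5d head E9.5 replicate 2 (9.19) lay above head E10.5 replicate 1 (9.10). The other arrays had Xist at 11.89 or more together with Eif2s3y at 8.02 to 9.35, above the median probe set. Ranks of Y-linked genes therefore cannot tell samples of males only from samples of mostly males. The design names no groups by sex, so no biological explanation beyond male embryos was tested, and 12 of the 349 genes called at E10.5 lie on chromosome X or Y.

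Other splits of the arrays gave far fewer genes than the split into head and trunk, but they cannot exclude chance differences between the samples. Each other split puts head and trunk arrays on the same side. The difference between the tissues then adds to its spread, which lowers its count. Nor do the labels say whether the arrays of a group come from separate animals. In a model with stage and tissue as terms the real split of the 12 arrays gave 621 genes, and of 100 splits drawn from 462 possible ones 1, the real one, gave as many; the highest of the others gave 2.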

How the results depend on the processing

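The settings that left out both E10.5 replicate 1 arrays, the genes of chromosomes X and Y, or the members of 5 cell type lists were chosen only after the data were seen; the other alternatives were planned. With 1 array left out, the lone array of its group is assumed to vary like the other groups, and the lowest and highest counts were 534 to 911 for head against trunk over the mean of the 3 stages, 238 to 452 at E9.5, 64 to 482 at E10.5 and 56 to 170 at E11.5. They were 173 to 395 for the change from E9.5 to E11.5 in head and 434 to 1078 in trunk, 2 to 135 and 105 to 578 from E9.5 to E10.5 in head and in trunk, 6 to 165 and 0 to 4 from E10.5 to E11.5, 57 to 120 for the difference between the changes, and 0.48 to 0.56 for the correlation between them. Without both E10.5 replicate 1 arrays the counts were 446 over the mean of the 3 stages, 34 for head against trunk at E10.5, 0 and 94 from E9.5 to E10.5 in head and in trunk, 4 and 0 from E10.5 to E11.5, and 63 for the difference between the changes; fewer arrays are part of these drops. With only the groups compared in the fit they were 679 at E10.5, 84 at E11.5, 213 for the whole change in head, 41, 48 and 4 for the steps E9.5 to E10.5 in head and E10.5 to E11.5 in head and in trunk, and 63 for the difference. Array weights gave 28 and 960 from E9.5 to E10.5 in head and in trunk, and 19 and 23 from E10.5 to E11.5. No low-signal filter gave 49 and 50 for the head steps and a correlation of 0.38 between the changes, an offset of 26.3 before log2 gave 117 for E9.5 to E10.5 in head and 13 for E10.5 to E11.5 in trunk, no intensity trend gave 192 at E10.5 and 34 for E9.5 to E10.5 in head, and the mean of probe sets gave 47 for the latter. Leaving out probe sets with the suffixes _s, _x and _a gave 224 at E10.5 and a correlation of 0.53. A fold of at least 2 as well, which adds a condition, left 315 over the mean of the 3 stages and 633 for the whole change in trunk. Without chromosomes X and Y 0 genes passed from E10.5 to E11.5 in trunk. Except where fewer arrays or an added condition are named, the cause was not tested. Whether the replicate numbers pair the samples is not settled. Deviations of 15 pairs of groups correlated by −0.3 to 0.17, and those of head and trunk by 0.01 at E9.5, −0.00 at E10.5 and −0.10 at E11.5, which does not show pairing. Xist, however, was low on replicate 1 of both tissues at E10.5, as pairing at that stage would give. With the numbers as a block E10.5 to E11.5 in head had 49 genes, and as a block by stage head against trunk at E10.5 had 213 against 349 and the difference between the changes 69 against 114. Of the list tests 138 passed, 16 with an estimated correlation, 114 on ranks, 106 with fry and 228 with fry in either direction, which does not compare a list with other genes. Quantile normalization, median centring, a stricter low-signal filter, robust variance and leaving out the cell type list members moved no count of called genes by more than 1.5 times. The arrays were already alike, so the first 2 had little to change. Leaving out the list members only dropped these genes after the fit and adjusted the p-values again. It removed no signal of other cell types from the remaining genes and does not test their part. Of 313 calls of named genes 134 were lost in at least 1 alternative, and 1 turned its sign, Tpm2 at E9.5, which was −0.27 without the probe sets with suffixes _s, _x and _a. Results of named genes that had not passed did so in 23 alternatives, among them Tcf21 at E11.5 in 7 and Lhx2 at E11.5 in 2. Of the values that had not passed, Isl1 in head over the whole change ran from −0.59 to 0.19 with single arrays left out, positive without head E9.5 replicate 2, and Myf5 in trunk from −0.16, without trunk E9.5 replicate 1, to 0.22, with −0.08 without trunk E11.5 replicate 2. Signals below the array median limit the folds of dim genes, which are given as bounds, and the differences between the changes, which are given also with such signals raised to that median.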

Other observations

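No test in this part was chosen after its result was seen. Unless a stage is named, the values are those of head against trunk over the mean of the 3 stages, by limma. The lists are those that the text above leaves out for this comparison.

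Several signalling genes, most of them lower in head, set the tissues apart. Aldh1a2, which makes retinoic acid, was at least 7.99-fold lower (log2 −3.40 ± 0.45, adjusted p = 0.000407), and with the reductase Dhrs3 (−0.79) and the binding protein Crabp2 (−0.69) it made 3 of 8 tested genes of the retinoic acid pathway lower and none higher, or 3 lower and 1 higher when adjusted over the list alone (median −0.30, camera adjusted p = 0.131). The Hedgehog co-receptors Boc (−1.61 ± 0.18, at least 2.88-fold), Cdon (−1.79 ± 0.38, at least 1.24-fold) and Gas1 (−0.54) were lower and the antagonist Hhip higher (0.65), 3 and 1 of 9 tested genes, or 3 and 2 when adjusted over the list alone (median −0.14, camera adjusted p = 0.113). The Wnt antagonists Nkd2 (−2.18 ± 0.30, at least 2.31-fold) and Wif1 (−1.65 ± 0.33, at least 1.70-fold) were the 2 of 16 Wnt pathway genes that were lower, or 4 when adjusted over the list alone (median −0.17, camera adjusted p = 0.0354; adjusted p = 0.155 with an estimated correlation). In the BMP and TGF-beta pathway the antagonists Fst (−1.17 ± 0.24, 2.26-fold) and Grem1 (−0.58) were lower and Id4 (0.74) and Bambi (0.78) higher, of 17 tested, or 3 and 3 when adjusted over the list alone (median 0.11, camera adjusted p = 0.866). At single stages Fst was −2.73 at E9.5 (adjusted p = 0.00203 by limma) and −0.96 at E10.5 (adjusted p = 0.184). It did not pass at E11.5, where Bmp5 was the only called member of this list (−1.60, adjusted p = 0.0389). In the Notch pathway Dll3 (−0.82) and Hes5 (−1.65) were the 2 of 17 genes that were lower, also when adjusted over the list alone; here the median was 0.08 and the mean 0.03, while the test pointed down (camera adjusted p = 0.962). In the FGF pathway 0 of 9 genes passed over all genes and 0 adjusted over the list alone (median −0.16, camera adjusted p = 0.554). Crabp2, Bambi, Id4, Hhip, Hes5, Grem1 and Dhrs3 lost their calls without single arrays, with an adjusted p of up to 0.141 for Crabp2 without trunk E11.5 replicate 1.

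Of 14 neural crest and ectomesenchyme genes the homeobox genes Dlx2 (log2 1.67 ± 0.17, at least 1.80-fold), Prrx2 (1.63 ± 0.18, 3.09-fold) and Dlx5 (2.24 ± 0.47) were higher in head and Twist1, a mesenchymal factor, lower (−1.51 ± 0.18, 2.85-fold), or 6 and 2 when adjusted over the list alone (median 0.43, camera adjusted p = 0.0195; adjusted p = 0.243 with an estimated correlation). In the cartilage list Sox6 (−0.59) and Sox9 (−0.79) were lower, 2 of 8, or 3 when adjusted over the list alone (median −0.26, camera adjusted p = 0.0623). Immediate early and heat shock genes, which respond to stress and dissociation, were higher in head for 6 of 18, or 9 when adjusted over the list alone (median 0.45, camera adjusted p = 4.16e-05; adjusted p = 0.183 with an estimated correlation), led by the phosphatase Dusp1 (0.89 ± 0.15, 1.85-fold) with Fos (0.54), Klf6 (0.57) and Nr4a1 (0.69). Among 29 cell cycle genes cyclin Ccnd2 was lower (−0.44 ± 0.07, 1.36-fold), also when adjusted over the list alone (median −0.20, camera adjusted p = 0.00486; adjusted p = 0.232 with an estimated correlation). In the hypoxia and glycolysis list Egln3 was higher (0.57) and P4ha1 lower (−0.48), 1 and 1 of 18, or 2 and 2 when adjusted over the list alone (median −0.06, camera adjusted p = 0.554). Of 4 X inactivation and Y-linked genes 0 passed over all genes and 0 adjusted over the list alone, with Xist at 0.15 (adjusted p = 0.941; list median 0.08, camera adjusted p = 0.902). Sox9 and P4ha1 lost their calls without single arrays, with an adjusted p of up to 0.114 for Sox9 without trunk E9.5 replicate 2.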
